A study of Mus musculus with 12 samples.

How the data were processed

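RNA from whole livers of mouse fetuses collected at 18.5 days post coitum was measured on 12 Affymetrix mouse gene arrays, with 6 arrays labelled wild type and 6 labelled double knockout for the histone variants macroH2A1 and macroH2A2. Per the labels' protocols, total RNA was extracted with Trizol and labelled with the Ambion WT Expression Kit. The labels give the same strain and male sex for every fetus, and separate replicate numbers from 1 to 6 within each genotype. Each array was taken as 1 fetus, which the labels imply without stating it. The tests therefore set the genotype difference against the spread between these 12 samples within genotypes. Which fetuses shared a recipient female, litter or day is not given in the labels. Fetuses that did may not be independent.

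The authors deposited log2 expression values per probe set, and per the submitters' processing notes the arrays were processed with Affymetrix Expression Console. Its version, the summarisation algorithm, the background correction and the genome build are not given in the sources used here. The log base was taken from the values, whose maximum lies under the log2 of a 16-bit scanner ceiling. Array medians lay between 7.55 and 7.61, so the arrays had been placed on a similar scale before deposit, but their spread differed. On double-knockout replicates 3, 5 and 6 and wild-type replicate 6, the 25th percentile was 6.21 to 6.28 and the 75th 9.05 to 9.10. On the other arrays these were 6.13 to 6.19 and 9.11 to 9.15. The table held 28815 probe sets and no column of per-sample values other than those of the 12 arrays. No pair of arrays was identical, with correlations over genes of at most 0.998. Scanner files were not used here, so background levels were not analysed here and a low value cannot be separated from background.

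Probe sets were named through the platform's gene table, which lists 23385 of them. Of these, 21780 name 1 gene and 1605 name several. The remaining 5430 are unlisted and stay unnamed here. Symbols were updated by gene ID through a reference gene table of assembly GRCm38.p6, in which 21689 listed probe sets were found. That table served only for names, chromosomes and the order of neighbouring genes, and 19853 genes were placed. For each of the 19935 genes with a probe set of its own, the probe set with the highest mean over the 12 arrays was used; 998 genes had more than 1.

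Genotypes were compared as double knockout minus wild type with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of adjusted p under 0.05. Values of p given for genes and lists come from these limma fits unless an exact permutation or Fisher test is named. A count at 1.5-fold or more was taken among the genes past the threshold. The script was tested on simulated data built from the 19935 genes of this comparison. It recovered 82% of 50 genes changed by 1.25-fold and 100% of 50 genes at each of 1.5-fold, 2-fold and 3-fold, with 9 false calls, or 4.5%. The simulation drew noise independently for each gene and changed many more genes than passed in the real comparison. A gene adjusted beside many true changes passes at a larger unadjusted p, so these shares do not give the power of the real comparison. The median standard error of a log2 fold change was 0.057, and the number of arrays limits this precision.

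The design, the alternatives, the named genes and 31 gene lists were fixed before the data were examined. The lists cover liver functions, cell types of fetal liver and neighbouring tissues, and checks of collection time and stress. Of their 720 entries, 655 were measured; 65 symbols were not, 21 of them because their probe set names several genes, and 7 symbols stand in more than 1 list. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, and beside it with camera at an estimated correlation, with fry and with an exact permutation of the list means over all splits of the arrays. Camera compares a list with all other genes, so its direction can differ from the sign of the list mean. X-linked genes were tested as 1 more list. Genes within 20 places of each targeted gene were compared with all others by Fisher's exact test. Principal components and the spread within genotypes were tested by exact permutation.

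The text names both targeted genes, every gene past the threshold, up to 12 in each direction apart from the targeted genes, and, in a direction where none passed, the 5 genes of smallest p. For each list it names the 3 members of smallest p, and Serpina7 and Lpl were named in advance. Any other gene is said to have been chosen after its values were seen. Alternatives were another normalization, a filter on dim genes, another prior, array weights, the replicate number as a block, marker means as covariates, other choices of probe set, and leaving out each array in turn. The pancreas covariate, the exact permutation of list means and leaving out both arrays of lowest weight were added after seeing the data. Figures were drawn with matplotlib 3.10.9.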

Results

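Livers of mouse fetuses labelled double knockout for both macroH2A histone variants were compared with livers labelled wild type at 18.5 days post coitum, to ask which genes depend on macroH2A in late fetal liver. Embryos of both genotypes had been mixed and carried by the same kind of wild-type recipient female. Each genotype was measured on 6 arrays, all labelled male. The array medians lay between 7.55 and 7.61 on the log2 scale, and all 12 arrays entered each comparison.

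Macroh2a1, which encodes macroH2A1, fell in the double knockout from 10.36 ± 0.13 to 9.59 ± 0.06 (log2 value, mean ± SD, n = 6 each; limma adjusted p = 3.5e-05). Its log2 fold change was -0.77 with a standard error of 0.06, or 1.71-fold lower, and every double-knockout array lay below every wild-type array. Macroh2a2, which encodes macroH2A2, measured 9.30 ± 0.15 in wild type and 9.21 ± 0.28 in the double knockout (SD, n = 6 each; limma adjusted p = 0.99). Its log2 fold change was -0.09 with a 95% interval from -0.33 to 0.15, and it became 0.0064 without double-knockout replicate 5. Each of these genes had 1 probe set. Where the probes lie relative to the deleted parts is not given in the sources used here, so the signal left in the knockout does not check the labels, and neither does that of Macroh2a2.

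**Figure D1:**
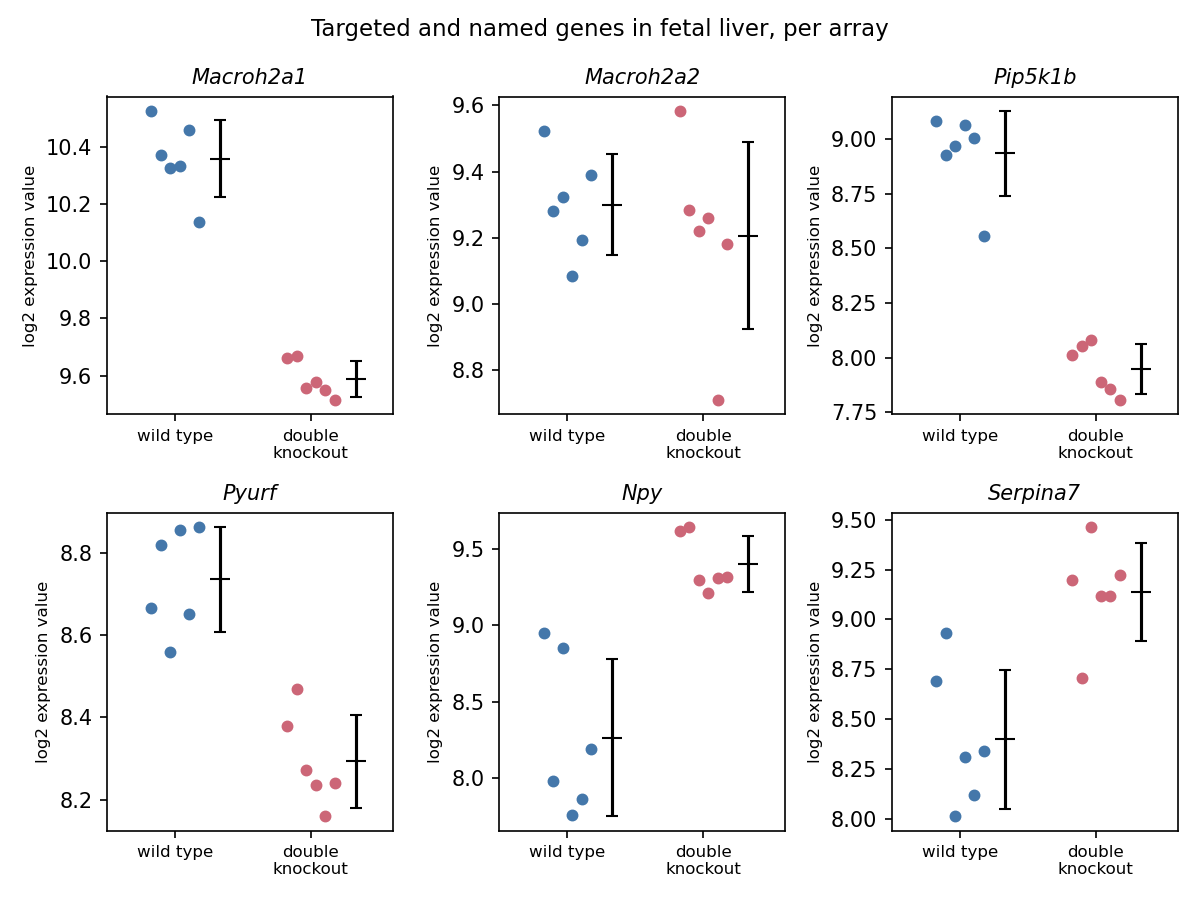
Log2 expression values of 6 genes on each array (points), with the mean and SD of each genotype beside them (black; n = 6 each); the axes do not start at 0. Macroh2a1, Pip5k1b and Pyurf lie lower on every double-knockout array than on any wild-type array and passed the test, whereas Macroh2a2 overlaps between genotypes and Npy and Serpina7 did not pass over all genes.

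Beyond Macroh2a1, 2 genes fell. Pip5k1b, which encodes a phosphatidylinositol phosphate kinase, dropped from 8.93 ± 0.19 to 7.95 ± 0.11 (log2 value, SD, n = 6 each; limma adjusted p = 6.4e-05), or 1.98-fold. Pyurf, which encodes a small mitochondrial protein, dropped from 8.74 ± 0.13 to 8.29 ± 0.11 (SD, n = 6 each; limma adjusted p = 0.047), or 1.36-fold. Both were lower in 6 of 6 double-knockout arrays than in any wild-type array. The call of Pyurf was lost in 10 of the 12 fits that left out 1 array, with adjusted p from 0.077 to 0.20, and held only without wild-type replicate 3 (0.024) or double-knockout replicate 2 (0.021); over its 22 alternatives the adjusted p ran from 0.021 to 0.34. With the targeted genes left out before adjustment, Pip5k1b alone passed.

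No gene rose past the threshold. The 5 genes of smallest p among those with higher means, none of which passed, were Npy, Serpina7, Prkg1, Gnat2 and Arl9. Npy, which encodes neuropeptide Y, measured 8.26 ± 0.51 in wild type and 9.40 ± 0.18 in the double knockout (SD, n = 6 each; limma adjusted p = 0.099), a log2 difference of 1.14 with a standard error of 0.19, and all 6 double-knockout arrays lay above every wild-type array. It passed without wild-type replicate 1 (adjusted p = 0.016) or wild-type replicate 3 (0.030), within a range of 0.016 to 0.40 over its alternatives. Serpina7, which encodes thyroxine-binding globulin and was named in advance, measured 8.40 ± 0.35 and 9.14 ± 0.25 (SD, n = 6 each), with 5 of 6 arrays above all of wild type. Its log2 difference was 0.74 with a 95% interval from 0.42 to 1.05. The limma p was 0.00018 unadjusted, which applies to a gene named in advance, and 0.35 adjusted over all genes. Prkg1, Gnat2 and Arl9 had log2 differences of 0.19, 0.18 and 0.22. Lpl, the lipoprotein lipase gene also named in advance, differed by -0.06 (limma unadjusted p = 0.22, adjusted p = 0.99).

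In total 3 of 19935 genes passed the limma test, all lower, and 2 of them by at least 1.5-fold. At unadjusted p under 0.05 there were 783 genes, 527 with higher and 256 with lower means, where chance gives 997. Without double-knockout replicate 2 the number lower became 6, through Ikzf3, Pou2af1 and Cd79a beside the same 3 genes; Ikzf3 and Pou2af1 were chosen after their values were seen. Without wild-type replicate 1 or 3 the number higher became 1, which was Npy.

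Markers of blood cells, which fetal liver makes, were examined as fixed lists. Of 21 lymphoid markers, 17 had lower means in the double knockout, with a list mean of 7.52 ± 0.06 in wild type and 7.39 ± 0.07 in the double knockout (log2, SD, n = 6 each; camera adjusted p = 7.6e-13). The adjusted p was 0.15 with an estimated correlation, 0.27 with fry's directional test and 0.40 by exact permutation of the list means, while fry's test for change in either direction gave 0.015. Pax5, the B cell commitment factor, differed by -0.23 on the log2 scale, Ebf1, an early B cell factor, by -0.38, and Cd79a, a chain of the B cell receptor, by -0.33. Adjusted over the list alone, 8 members passed, all lower, while 0 passed over all genes tested. Of 23 markers of neutrophils and their precursors, 22 had lower means, with a list mean of 10.33 ± 0.07 and 10.23 ± 0.08 (log2, SD, n = 6 each; camera adjusted p = 1.4e-12), and adjusted p = 0.16 with an estimated correlation. Chil3 differed by -0.41 and was the 1 member past the threshold adjusted over the list alone; Cd177 and Ltf, which encodes lactoferrin, differed by -0.19 and -0.14.

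The other blood lists did not pass. Of 23 erythroid markers 14 had higher means (camera adjusted p = 0.92), with Tspan33 at -0.23, Car1 at 0.15 and Trim10 at 0.14. Without wild-type replicate 6 Car1 differed by 0.08 and Trim10 by 0.06, and Trim10 by 0.09 without double-knockout replicate 5; the list mean of wild-type replicate 6 was 11.02, against 11.30 for the next lowest wild-type array. Without that replicate the erythroid list passed as lower (adjusted p = 0.017), as it did without both arrays of lowest weight (0.00025, within 0.00025 to 0.999 over its alternatives). Of 13 megakaryocyte and platelet markers 8 had higher means (adjusted p = 0.78), with Vwf at -0.10, Itga2b at -0.06 and Thbs1 at -0.06. Of 20 macrophage markers 10 had lower means (adjusted p = 0.34), with Timd4 at -0.11, Vsig4 at 0.23 and Fcgr1 at -0.09; this list passed without double-knockout replicate 4 (adjusted p = 0.042, within 0.042 to 0.98 over its alternatives).

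**Figure D2:**
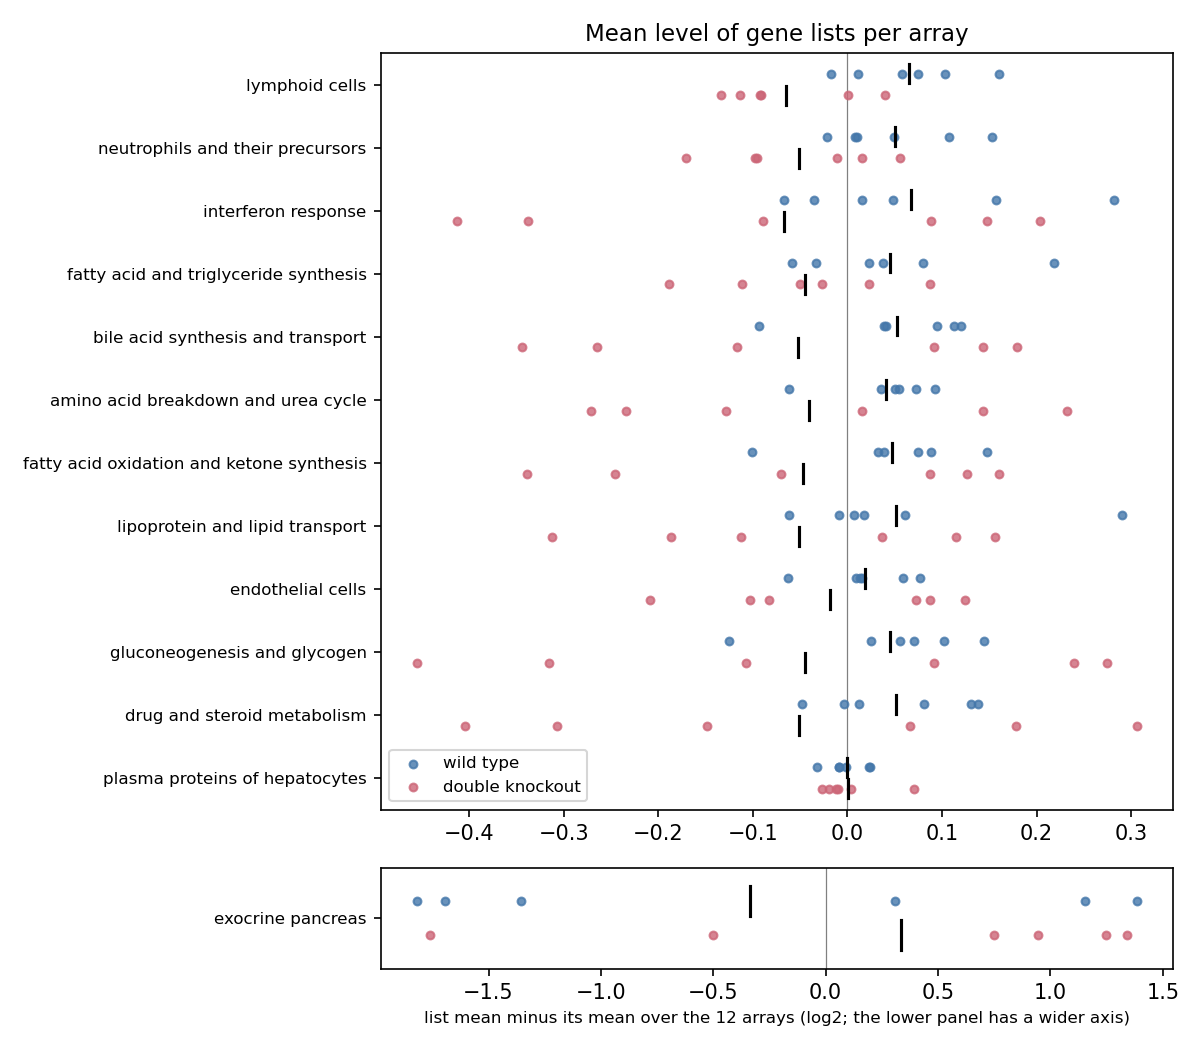
Mean log2 level of each gene list that passed camera with the preset correlation, per array, relative to its mean over the 12 arrays (points; n = 6 per genotype), with black bars for genotype means; the lower panel has a wider axis. Genotypes overlap in every list shown, and the exocrine pancreas list spans 3.20 log2 units between arrays.

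Of the 4 lists of lipid metabolism, 3 passed camera as lower than other genes and the cholesterol list had a higher mean. Of 25 genes of fatty acid and triglyceride synthesis, 23 had lower means, with a list mean difference of -0.09 (camera adjusted p = 5.2e-07; adjusted p = 0.63 with an estimated correlation). Srebf1, the regulator of lipid synthesis genes, differed by -0.20, Fasn, fatty acid synthase, by -0.18 and Scd1, a desaturase, by -0.28. Without wild-type replicate 4, the highest array for this list at 10.58, the list mean difference was -0.054 and Scd1 differed by -0.18, as it did without double-knockout replicate 3. Fatty acid oxidation and ketone synthesis had 23 of 25 members lower (camera adjusted p = 2.8e-05; adjusted p = 0.78 with an estimated correlation), with Acot1 at -0.27, Cpt1a, which brings fatty acids into mitochondria, at -0.17 and Ppara at -0.15. Its list mean difference of -0.09 became -0.054 without double-knockout replicate 3 and -0.035 without double-knockout replicate 5. Lipoprotein and lipid transport had 21 of 28 lower (camera adjusted p = 0.0024; adjusted p = 0.78 with an estimated correlation), with Cd36 at 0.14, Scarb1 at -0.16 and Fabp2 at -0.82. Fabp2 measured 10.17 on wild-type replicate 6, which also had the highest mean of the intestine and stomach list, 8.34 on replicate 5 and 7.01 to 7.34 on the other wild-type arrays. Without replicate 6 its difference was -0.37. The lipoprotein call was lost without wild-type replicate 6 (adjusted p = 0.099), where the list mean difference went from -0.10 to -0.054, or without double-knockout replicate 5 (0.28), where it was -0.049. Cholesterol synthesis and uptake had 13 of 20 members higher and did not pass (camera adjusted p = 0.20), with Stard4 at 0.11, Msmo1 at 0.23 and Idi1 at 0.22; it passed in 4 of the 12 fits without 1 array, namely wild-type replicates 2 (0.045), 4 (0.0079) and 5 (0.028) and double-knockout replicate 1 (0.0088, difference 0.09), and also after quantile normalization (0.035) and among genes above the median gene level (0.017). The cholesterol list mean difference of 0.06 was smaller without wild-type replicate 6, at 0.019 (adjusted p = 0.98), and without wild-type replicate 3, at 0.036 (0.69).

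Double-knockout arrays differed among themselves in other hepatocyte functions. Bile acid synthesis and transport had 21 of 22 members lower (camera adjusted p = 8.5e-06; 0.78 with an estimated correlation), with Baat at -0.24, Akr1d1 at -0.25 and Abcb11, the bile salt export pump, at -0.24. Amino acid breakdown and the urea cycle had 18 of 21 lower (camera adjusted p = 9.1e-06; 0.78 with an estimated correlation), with Bhmt at -0.19, Glul at -0.19 and Asl at -0.13. Gluconeogenesis and glycogen had 12 of 16 lower (camera adjusted p = 0.014, and 0.78 with an estimated correlation), with Pcx at -0.13, G6pc, glucose-6-phosphatase, at -0.41 and Fbp1 at -0.06. Drug and steroid metabolism had 15 of 24 lower (camera adjusted p = 0.030, and 0.78 with an estimated correlation), with Aox3 at -0.14, Cyp1a2 at 0.10 and Fmo5 at -0.28. In the bile acid list, double-knockout replicates 1, 2 and 4 had means of 9.95, 9.92 and 9.86, above the wild-type mean of 9.82, and replicates 3, 5 and 6 had 9.51, 9.43 and 9.66. Replicates 3, 5 and 6 also had a narrower spread of values over all probe sets than replicates 1, 2 and 4. The bile acid call was kept after quantile normalization. The bile acid difference of -0.10 became -0.061 without double-knockout replicate 3 and -0.046 without replicate 5. In the amino acid list, the 6 double-knockout arrays had means of 11.47, 11.38, 11.01, 11.26, 10.97 and 11.11 in order, against a wild-type mean of 11.28, and the difference of -0.08 became -0.14 without double-knockout replicate 1, -0.042 without replicate 3 and -0.035 without replicate 5. G6pc measured 10.47 on double-knockout replicate 5, 11.17 on replicate 3 and 12.04 to 12.31 on the other 4, and differed by -0.15 without replicate 5. Without that array Pcx differed by -0.08, Abcb11 by -0.14, Glul by -0.09, Asl by -0.07, Aox3 by -0.08 and Fmo5 by -0.18. The gluconeogenesis call was lost without wild-type replicate 3 (0.076) or 6 (0.11) or double-knockout replicate 3 (0.27) or 5 (0.69); its difference of -0.09 ran from -0.15 without double-knockout replicate 1 to -0.0087 without replicate 5, and was -0.15 without replicate 2 and -0.037 without replicate 3. The drug metabolism call was lost without wild-type replicate 4 (0.069) or 6 (0.27) or double-knockout replicate 3 (0.26), 5 (0.29) or 6 (0.11); its difference of -0.10 was -0.17 without double-knockout replicate 1, -0.052 without replicate 3 and -0.033 without replicate 5.

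Plasma proteins of hepatocytes had 21 of 28 members lower and a median of -0.02, while the list mean was 0.0017; camera placed the list lower than other genes (adjusted p = 0.046; adjusted p = 0.78 with an estimated correlation). Serpina7 was the 1 member past the threshold adjusted over the list alone, and Mbl2 and F12 differed by -0.18 and -0.10. The call was lost in 7 of the 12 fits without 1 array, with adjusted p from 0.051 to 0.32: wild-type replicates 2 (0.062), 3 (0.13) and 6 (0.32) and double-knockout replicates 2 (0.20), 3 (0.26), 5 (0.26) and 6 (0.051). Interferon response genes had 20 of 22 members lower, with a list mean of 8.48 ± 0.13 and 8.34 ± 0.26 (log2, SD, n = 6 each; camera adjusted p = 2.5e-07), and adjusted p = 0.78 with an estimated correlation. Ifi35 differed by -0.14, Stat2, which carries the interferon signal, by -0.17 and Oas2 by -0.24, or -0.16 without wild-type replicate 6. Double-knockout replicates 1, 2 and 4 had list means of 8.56, 8.50 and 8.61, above the wild-type mean, and replicates 3, 5 and 6 had 8.07, 8.00 and 8.32; the difference of -0.13 became -0.079 without replicate 3 and -0.064 without replicate 5. Endothelial markers had 16 of 20 lower (camera adjusted p = 0.0031, and 0.78 with an estimated correlation), with Flt4 at -0.11, Dnase1l3 at -0.17 and Robo4 at -0.07. Over their 22 alternatives Flt4 ran from -0.14 to -0.070, Dnase1l3 from -0.22 to -0.018 and Robo4 from -0.095 to -0.034. The endothelial call was lost without wild-type replicate 6 (camera adjusted p = 0.092) or double-knockout replicate 5 (0.28). The endothelial difference of -0.04 was -0.058, -0.024, -0.065, 0.0012 and -0.020 without double-knockout replicates 2, 3, 4, 5 and 6 in turn.

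Exocrine pancreas markers, which a liver sample holds only with neighbouring tissue, had 17 of 17 members with higher means (camera adjusted p = 0.0068; adjusted p = 0.78 with an estimated correlation). Their list mean was 8.78 ± 1.46 in wild type and 9.45 ± 1.22 in the double knockout (log2, SD, n = 6 each; exact permutation p = 0.37). Cel, a lipase, differed by 1.12, Cela3b by 0.59 and Cpb1 by 1.09. The camera call was lost without wild-type replicate 1 (0.46), 2 (0.14) or 3 (0.14) or double-knockout replicate 4 (0.054), 5 (0.17) or 6 (0.25). The list mean difference of 0.67 was 0.38 and 0.40 without wild-type replicates 1 and 3, 1.02 without wild-type replicate 5 and 1.09 without double-knockout replicate 3. These markers were near 7.3 on wild-type replicate 1 and reached 10.5 on wild-type replicate 5, beside every gene group above.

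Growth, imprinting and proliferation lists did not pass in the planned main comparison of the 12 arrays. Imprinted genes had 19 of 31 members higher (adjusted p = 0.94), with Zim1 at 0.18, Slc22a18 at -0.10 and Plagl1 at 0.11. Fetal liver genes had 8 of 16 lower (adjusted p = 0.098), with Igf2bp3 at -0.12, Tmem98 at -0.20 and Tff3 at -0.15; they passed without wild-type replicate 1 (0.026) or double-knockout replicate 5 (0.044). The insulin-like growth factor and growth hormone axis had 14 of 20 lower (adjusted p = 0.082), with Insr at -0.10, Igf1r at -0.08 and Igf2 at -0.05, and passed in 6 of the 12 fits without 1 array (adjusted p from 0.019 to 0.045), namely wild-type replicates 1, 2 and 5 and double-knockout replicates 1, 2 and 4, and with the replicate block or camera on ranks (0.039 each). Proliferation genes had 16 of 31 higher (adjusted p = 0.68), with Bub1 at 0.12, Nusap1 at 0.08 and Ccne2 at -0.07; they passed as lower without wild-type replicate 6 (0.0017) or double-knockout replicate 3 (0.040) or 5 (0.021), and without both arrays of lowest weight (3.6e-08, mean -0.093). Histone genes related to macroH2A had 12 of 18 higher (adjusted p = 0.94), with Asf1a at 0.07, Atrx at 0.06 and H2ax at -0.14, and passed as lower without both arrays of lowest weight (0.041, mean -0.047).

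Stress and time-of-collection lists did not pass either. The p53 response and senescence list had 10 of 15 members higher (adjusted p = 0.91), with Perp at -0.13, Eda2r at 0.08 and Cdkn2b at 0.07. Endoplasmic reticulum stress genes had 14 of 21 higher (adjusted p = 0.94), with Atf5 at -0.20, Chac1 at 0.17 and Sel1l at -0.08. Acute phase genes had 18 of 24 lower (adjusted p = 0.085), with Hamp, which encodes hepcidin, at 0.63, Itih4 at -0.08 and Mt2 at 0.06, and passed without wild-type replicate 5 (0.011) or double-knockout replicate 1 (0.0056) or 4 (0.047), or with the replicate block (0.0495). Circadian clock genes had 12 of 18 lower (adjusted p = 0.098), with Per2 at -0.11, Tef at -0.10 and Cry2 at -0.09, and passed without wild-type replicate 5 (0.034) or double-knockout replicate 1 (0.019) or 4 (0.040). Immediate early and heat shock genes had 10 of 19 higher (adjusted p = 0.91), with Zfp36 at -0.16, Hsph1 at 0.09 and Dnaja1 at 0.06.

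Remaining cell type lists did not pass. Stellate and other mesenchymal markers had 15 of 24 members higher (adjusted p = 0.92), with Lum at 0.21, Pdgfra at 0.12 and Ecm1 at -0.15. Bile duct and hepatoblast markers had 10 of 15 higher (adjusted p = 0.92), with Cldn4 at 0.12, Pdgfa at 0.06 and Sox4 at 0.06. Mesothelial markers had 10 of 14 higher (adjusted p = 0.71), with Pkhd1l1 at 0.21, Gpm6a at 0.12 and Alcam at 0.07. Intestine and stomach markers had 11 of 21 lower (adjusted p = 0.26), with Fabp6 at 0.08, Krt20 at -0.21 and Defa24 at -0.08, and passed as lower with the pancreas covariate (0.038).

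Across the 31 lists, 12 passed camera as lower and 1 as higher. The preset correlation was 0.01, whereas the correlations estimated for these lists ran from 0.19 to 0.93. Double-knockout replicates 3 and 5 were the lowest arrays in the fatty acid, lipoprotein, gluconeogenesis, bile acid, drug, amino acid and interferon lists. Those calls are therefore not independent of each other. With an estimated correlation, with fry's directional test and by exact permutation of the list means, 0 lists passed. The arrays allow too few splits for any list to pass the exact permutation alone after adjustment over the 31 lists. The adjusted 0 therefore says little by itself. Without adjustment, the exact permutation p was 0.013 for the lymphoid, 0.052 for the neutrophil and 0.16 for the fatty acid synthesis list. It ran from 0.29 to 0.93 for the other lists that passed camera. Of the 655 entries measured, 36 had unadjusted p under 0.05, 26 lower and 10 higher, and 0 passed in limma over all genes; adjusted over the list alone, 28 lists had 0 members past the threshold. Camera's direction was lower while list mean and median were positive for the histone, proliferation, endoplasmic reticulum stress, immediate early, erythroid and megakaryocyte lists. Without wild-type replicate 6 and double-knockout replicate 5, which had the lowest array weights of 0.449 and 0.566, 7 lists passed: the lymphoid, neutrophil, fatty acid synthesis and pancreas lists kept their calls, and the histone, proliferation and erythroid lists gained one as lower. These calls too used the preset correlation, and camera at an estimated correlation was not run there.

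X-linked genes were compared with autosomal genes because macroH2A is enriched on the inactive X chromosome. The 739 X-linked genes had a mean log2 fold change of 0.03 and the 19103 autosomal genes 0.01 (camera p = 0.039 for the X-linked genes; p = 0.12 with an estimated correlation). The difference between X-linked and autosomal means, taken per array, gave an exact permutation p of 0.030. Xist, the RNA that coats the inactive X, was chosen after its values were seen: it measured 12.98 ± 0.06 in wild type and 12.95 ± 0.04 in the double knockout (log2, SD, n = 6 each; limma adjusted p = 0.99). On the 12 arrays, all labelled male, Xist lay between 12.91 and 13.08, above 99.5% of genes. The Y-linked genes Kdm5d, Uty and Eif2s3y, also chosen after their values were seen, had means of 5.15, 4.76 and 4.13, where the median gene had 7.81. These levels go against the label, so the arrays are described as labelled male.

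**Figure D3:**
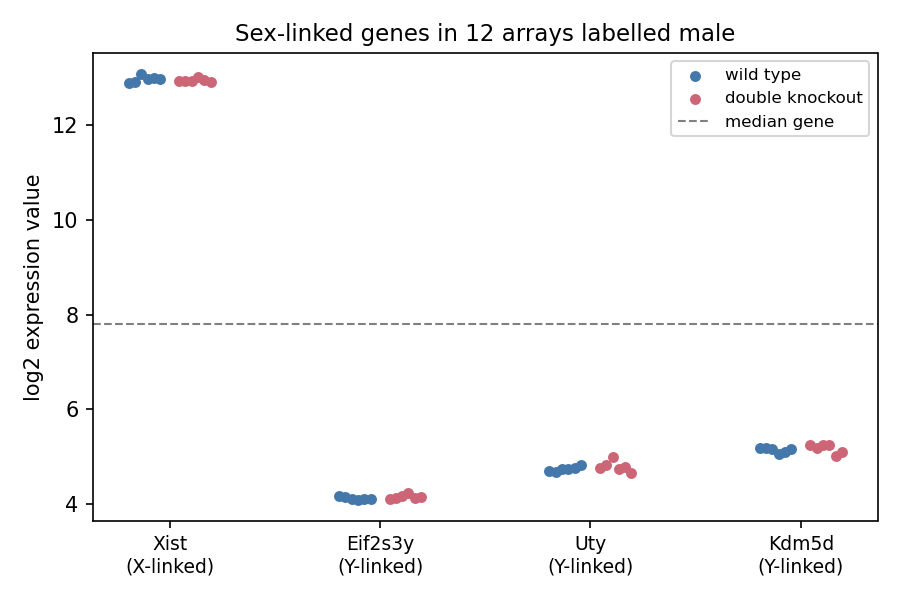
Log2 expression values of Xist and of 3 Y-linked genes on the 12 arrays labelled male (points, by genotype), with the median gene level as a dashed line. Xist lies between 12.91 and 13.08 and the Y-linked genes lie below the median gene of 7.81 on every array.

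Genes that neighbour Macroh2a1 on chromosome 13 and Macroh2a2 on chromosome 10 could carry effects of the targeting itself. Of the 80 genes within 20 places on either side of these loci, 0 passed the limma test, against 2 of the 19853 other genes (Fisher's exact p = 1.0). With so few genes past the threshold anywhere, a count of 0 was nearly certain beforehand, so it cannot decide whether the targeting affected neighbours. At unadjusted p under 0.05 there were 4, or 5.0%, against 3.92% of the others (Fisher's exact p = 0.56).

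Genotype did not separate the arrays as a whole. The first principal component held 30.5% of the variance and the second 21.0%, with exact permutation p for genotype of 0.43 and 0.89. Arrays of different genotype correlated over genes with a median of 0.996, against 0.996 within wild type and 0.994 within the double knockout. The median over genes of the SD between fetuses was 0.092 in wild type and 0.097 in the double knockout. Taken gene by gene, the median log2 ratio of the double-knockout SD to the wild-type SD was 0.11 (exact permutation p = 0.53). Without wild-type replicate 6 the ratio was 0.33 (exact permutation p = 0.015).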

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

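Each value here is the gap of 1 array to its nearest neighbour divided by the range of its genotype, and 14 of 300 groups of 6 exceeded the 5% limit of Dixon's outlier test, where chance gives about 15. Wild-type replicate 6 recurred among them. It was low for Pip5k1b (0.705), for the erythroid genes Car1 (0.688) and Trim10 (0.659), for the erythroid list mean (0.733) and for the list of histone genes related to macroH2A (0.674), and high for the lipoprotein list (0.652) and the intestine and stomach list (0.632). Wild-type replicate 5 was low for Cpt1a (0.689) and for the amino acid breakdown and urea cycle list (0.629).

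In the double knockout, replicate 5 was high for Eda2r (0.629), and replicate 4 was high for Oas2 (0.641) and for Xist (0.657). Replicate 1 was high for the plasma protein list (0.677), and replicate 6 was low for the fetal liver list (0.655).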

How the results depend on the processing

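The pancreas covariate, the exact permutation of list means and leaving out both arrays of lowest weight were chosen after seeing the data; the other alternatives were planned. Macroh2a1 and Pip5k1b passed as lower in all 22 alternatives fitted for every gene, with log2 fold changes of -0.81 to -0.74 and -1.06 to -0.94, and Pyurf passed in 8. The number of genes lower ran from 2 to 6 and the number higher from 0 to 1 when 1 array was left out, and the number higher was 1 with the pancreas covariate (Npy); the cause was not tested. Macroh2a2 became 0.025 without both arrays of lowest weight and ranged from -0.17 to 0.0064 without 1 array, past the threshold in none of them. The number of lists that passed was 0 with an estimated correlation, 0 with fry's directional test and 0 by exact permutation, which allow for correlation between genes, and 7 without both arrays of lowest weight. The exact permutation has too few splits for a list to pass alone after adjustment, so its 0 says little by itself. Without adjustment, only the lymphoid list among those that passed camera had an exact permutation p under 0.05 (0.013). Fry's test for change in either direction passed 1 list, the lymphoid one. The call of X-linked genes, with a mean of 0.025 and p = 0.039, was lost with an estimated correlation (p = 0.12). The spread ratio ran from 0.031 to 0.33 without 1 array.

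Of 2550 alternatives for 117 named-gene results apart from the targeted genes, 2529 kept direction and side of the threshold, 14 lost and 7 gained the call, and 0 reversed. Most of these genes lay far from the threshold and were picked for small p, so keeping direction and side was likely beforehand. The 14 lost calls were all those of Pyurf, out of its 22 alternatives. The log2 fold change of 52 of these 117 genes moved over 1.5 times without some single array, as did the mean of 29 of the 31 lists. Of 804 alternatives for the 31 lists, 605 kept direction and side, 82 lost and 25 gained the call and 92 reversed. Of the reversed, 77 had neither value past the threshold, and the cause was not tested. With each array centred on its median the list means became -0.0096 for the histone list, -0.0099 for plasma protein, -0.010 for proliferation, -0.0018 for p53, -0.0086 for immediate early, -0.0073 for megakaryocyte and -0.0074 for bile duct. With genes above the median gene level the list means became -0.0032 for the histone list, -0.0019 for plasma protein, -0.0075 for p53, -0.017 for immediate early, -0.0067 for bile duct and 0.31 for intestine. With array weights the list means became -0.015 for the histone list, -0.021 for proliferation, 0.0027 for acute phase, -0.012 for erythroid and 0.043 for intestine. With the erythroid covariate the list means became -0.0068 for the histone list, -0.014 for proliferation and 0.0056 for intestine. Without both arrays of lowest weight the list means became -0.047 for the histone list (call gained), -0.0019 for plasma protein, 0.029 for growth factor, -0.093 for proliferation (call gained), -0.0066 for endoplasmic reticulum stress, 0.029 for acute phase, -0.061 for erythroid (call gained), 0.016 for macrophages, 0.0094 for endothelial and 0.065 for intestine. With the pancreas covariate the list means became 0.0022 for the acute phase list, 0.0034 for macrophages and -0.013 for bile duct. After quantile normalization the list means became -0.0046 for the immediate early list, 0.00039 for macrophages and -0.010 for bile duct. Leaving out 1 array at a time gave list means of -0.038 to 0.019 for histone, -0.012 to 0.0073 for plasma protein, -0.030 to 0.0020 for fetal liver, -0.050 to 0.024 for growth factor, -0.060 to 0.037 for proliferation, -0.012 to 0.035 for p53, -0.0038 to 0.031 for endoplasmic reticulum stress and -0.034 to 0.026 for acute phase. It gave -0.036 to 0.012 for clock, -0.0090 to 0.023 for immediate early, -0.042 to 0.037 for erythroid, -0.030 to 0.038 for megakaryocyte, -0.028 to 0.026 for macrophages, -0.065 to 0.0012 for endothelial, -0.0048 to 0.052 for stellate, -0.020 to 0.035 for bile duct and -0.040 to 0.077 for intestine. Other settings ended the call of the lipoprotein list (genes above the median gene level, camera adjusted p = 0.21; array weights, 0.057), gluconeogenesis (quantile normalization, 0.092; genes above the median, 0.21; array weights, 0.086) and drug metabolism (quantile normalization, 0.067; median centring, 0.066; array weights, 0.13). They also ended that of plasma proteins with quantile normalization (0.50), genes above the median (0.41), array weights (0.14), the erythroid covariate (0.073) or the mean of all probe sets (0.0503), and that of endothelial markers with genes above the median (0.093). The erythroid list under its own covariate and the pancreas list under its own gave no value.

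The replicate numbers share only a number: deviations of same-numbered arrays correlated between -0.18 and 0.49, over 0.1 in 5 of 6 pairs, and 4 wild-type arrays correlated best with their own number, which is a hint from the data and not from the design. With the replicate block, 2 genes were lower, 0 higher and 15 lists passed. The genes were Macroh2a1, which stayed at -0.77, and Pip5k1b, while Pyurf lost its call. Signal over background was not analysed here, which limits statements on dim genes.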

Other observations

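The tests given here of the lymphoid markers, of the chromosome 6 genes and of the sex label were chosen after the data were examined, as were those of the number of genes and of the smallest p with the targeted genes left out. For a single fetus and for pancreas tissue, what would count against them was written before the result was seen, but the exact permutation and the pancreas covariate they rest on were added after the data were examined. The tests of runs of neighbouring genes and of the number of all genes past the threshold were written before their results were seen. All genes named here beyond those of the lists, Macroh2a1, Pip5k1b, Pyurf and Npy were chosen after their values were seen. Among B-lineage genes outside the list, 4 were picked because they were lower: Ikzf3, which encodes the lymphoid factor Aiolos, differed by -0.33 on the log2 scale (limma adjusted p = 0.096), Pou2af1, a B cell coactivator, by -0.39 (adjusted p = 0.15), Spib by -0.51 (adjusted p = 0.91) and Irf4 by -0.26 (adjusted p = 0.99). None of them passed, and being picked for their direction they carry no evidence on it. Within the lymphoid list, split after its values were seen, the 12 B-lineage members had a mean difference of -0.18 with 10 lower, and the 6 T and NK members -0.03 with 4 lower. Their wild-type means were 7.80 and 6.66, where the median gene had 7.81, so a fall of the dimmer T and NK members could be missed. The difference between these subsets was not tested.

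Lower lymphoid markers in the double knockout were weighed against chance, a loss of blood cells, a single fetus and pancreas tissue. Among all splits of the 12 arrays into equal groups, a difference in the list mean as large came from 6, the real one included, which argues against chance for this list taken singly but not after adjustment over the 31 lists (adjusted p = 0.40). No list could pass alone after that adjustment with the splits available. The lymphoid list lay above the smallest p these splits allow, with 6 splits as large, so chance stays open for it. The lymphoid mean still differed from that of the erythroid, megakaryocyte and macrophage lists (exact permutation p = 0.0065). It also differed from that of these lists and the neutrophil list together (exact permutation p = 0.019). This contrast was chosen after the lists were seen and was not repeated without single arrays. Without wild-type replicate 6 the erythroid list mean difference was -0.042. The contrast therefore cannot decide on a loss of blood cells of every kind. A single fetus is argued against, since the highest exact permutation p without 1 array was 0.026. Pancreas tissue is argued against too, since the covariate left 1.02 times the difference. The neutrophil list also had a lower mean, by -0.10 with 22 of 23 members lower, and a fall shared by lymphoid cells and neutrophils cannot be told apart from a lymphoid one, since the lymphoid mean minus the neutrophil mean gave an exact permutation p of 0.53. A smaller share of these cells in livers labelled double knockout, or lower expression per cell, may account for the pattern; both stay open and untested.

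Genes close together on chromosome 6 stood out among those of smallest p. Npy, Pde1c, Herc6 and Pyurf are 4 of the 20 genes of smallest p and lie within 76 neighbouring genes. This stretch holds 7 genes with limma unadjusted p under 0.01, the others being Osbpl3, Chn2 and Nod1, which differed by -0.27, -0.23 and -0.24. The stretch was drawn around genes of small p, so this count does not test the grouping. A test written beforehand looked for runs of 30 neighbouring genes with p under 0.01; 32 of 100 splits gave a run as large as the real 5, with 23 as the highest other, and the real run was on chromosome 3 (Usp53, Ndst4, Ank2, Fam241a and 1810037I17Rik), so chance could not be excluded. A second test, chosen because the first did not point to chromosome 6, asked how many of the 20 genes of smallest p fall within 100 neighbouring genes: 8 of 100 splits gave as many as the real 4, with 9 as the highest other, so chance could not be excluded here either, nor with 50 genes (12 splits) or 200 (10 splits). Different blood cell content cannot be told apart from other causes: lymphoid and erythroid covariates left 0.675 of the median size of the 4 differences, but these genes were picked for their small p; linkage to a targeted locus is argued against, with 0 targeted genes on that chromosome, a passenger segment from another strain was not tested, and the grouping may be chance given the 8 splits.

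The levels of sex-linked genes argue against the male label on all 12 arrays. Cross-hybridisation at the Xist probe set is argued against, since 0 of the 3 measured Y-linked genes lay above the median gene level, while Xist lay above 99.5% of genes, which is consistent with female tissue. The means of Eif2s3y, Uty and Kdm5d lay above only 0.24%, 3.07% and 6.87% of genes, and Xist was at least 12.91 on every array. These values argue against male tissue, so an inactive X was probably present in the X-linked comparison. The sex was read from these same arrays and was not tested in another way.

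The number of genes past the threshold was tested on other groupings of the arrays. Of 100 splits, 2 gave as many genes past the threshold, the real one with 3 included, and the highest of the others was also 3, but the real count holds Macroh2a1, whose fall the design sets. Counting the other genes gave 2, reached by 2 of 100 splits; with the targeted genes left out before adjustment 1 gene remained, 7 of 100 splits gave as many and the highest other gave 3, so the number of genes does not exclude chance. For Pip5k1b chance is argued against, since the smallest p apart from the targeted genes was reached by 1 of 100 splits, the real one, with a negative log10 p of 8.19 and 5.995 as the highest other; Pyurf lost its call in 10 of the 12 fits without 1 array, and chance stays open for it. At unadjusted p under 0.05, 54 of 100 splits gave as many as the real 783, and the highest other gave 2937; what sets such splits apart was not tested.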
